A study of Homo sapiens with 12 samples.

How the data were processed

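RNA from FULVR cells given a control siRNA or 1 of 3 VGLL1 siRNAs, 3 libraries per group, was extracted with RNeasy columns and made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. The control siRNA's sequence, the siRNA sequences, the dose and the time after transfection are not given in the sources used here. Reads were processed by the authors with TopHat, SAMtools, HTSeq and DESeq2 against hg19, per the submitters' processing notes, and versions, options and the gene annotation are not given in the sources used here. The deposited table holds the signal of each gene in each library as read counts that the authors divided by a DESeq2 size factor, per the submitters' processing notes and as checked on the values. It has 27911 genes and 12 libraries, and every column was used.

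The division was tested on the file. In each library 100% of the values were whole multiples, within a tolerance of 0.01 reads, of the value of 1 read, so that whole reads could be recovered. The size factors found in this way, from 0.846 to 1.09, equalled median-of-ratios factors computed from the recovered reads with a spread of 2.55e-09%. Recovered reads in genes ran from 13892258 to 17148686 per library. A gene at the mean filter of 10 rested on about as many reads per library, and the error of each comparison came from the 3 libraries per group. PCR copies were not marked, so counting error is a lower limit.

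Log2 of the deposited value plus 1 was analysed with limma 3.58.1 (trend option) in R 4.3.3. Genes with a mean of at least 10 over the 12 libraries were tested, 13441 of 27911, and 7001 genes were at 0 in every library. The 4 group means were fitted in 1 linear model, and 7 comparisons were drawn from it: each siRNA against control, the mean of the 3 siRNAs against control, and the 3 pairs of siRNAs. All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Genes changed the same way by all 3 siRNAs passed in each with the same sign, and their number was set against simulated unchanged groups and against independent lists. Chosen after the result was seen, such genes were also called without 1 control library and set against that library. Covariances and the signs of called genes were also computed, after the result was seen, with a separate control library for each siRNA.

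Before the data were examined, 31 gene lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed. The lists covered VGLL, TEAD and Hippo genes, targets of YAP and TEAD, EGFR and MAPK signalling, oestrogen receptor, luminal, basal, mesenchymal and trophoblast genes, adhesion, cell cycle and growth, metabolism, stress, interferon and apoptosis, the RNA interference machinery and markers of fibroblasts, endothelial cells and leukocytes. The 29 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation.

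Genes named were the VGLL and TEAD genes, YAP1, WWTR1, EGFR and ESR1. To these came the 12 rises and 12 falls with the largest smallest effect among genes with a mean of at least 50 changed the same way by all 3 siRNAs. For each siRNA up to 4 genes with the largest difference from control that also passed against both other siRNAs were named, and up to 4 examples per list. Any other gene named was chosen after its values were seen. Symbols may share reads with near-identical copies, above all those of the IFIT, keratin, HSPA6, AKR1C and ribosomal protein genes, and how such reads were assigned is not given in the sources used here.

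Alternatives changed the pseudocount (0.5 or 5), the filter (none or a mean of 50), the scaling (TMM or quantile), the test (edgeR 4.0.16 or DESeq2 1.42.0 on recovered reads, or robust moderation), the grouping, the libraries fitted and a block for replicate number. Added after the data were seen were an average over siRNAs 2 and 3, thinning of reads to the smallest library and a 1.5-fold minimum. The procedure was tested on simulated data with 13441 genes and known changes, far fewer than were called in the data. It recovered 87.9%, 88.9% and 87.3% of 2-fold changes for siRNAs 1, 2 and 3, and 52%, 47.5% and 50% of 1.25-fold rises, with 6.29%, 3.95% and 8.33% of calls false.

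For seed matches, the presence of each of 15946 words of 7 bases in the 3' UTR was related to the difference of each siRNA from the other 2 over 12167 tested genes with a 3' UTR of at least 50 bases, with 100 shuffles. The relation was adjusted for the length and GC content of the 3' UTR and for the mean level of the gene. UTR sequences came from GENCODE v29 on GRCh38 and were joined by gene symbol. Since the authors' build differs, no coordinates are given. Closing tests and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.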

Results

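RNA was sequenced from FULVR, a human breast cancer cell line derived from MCF7 and resistant to fulvestrant, a drug that degrades the oestrogen receptor. Cells received a control siRNA or 1 of 3 different siRNAs against VGLL1, a vestigial-like co-factor that binds TEAD transcription factors. Each of the 4 groups held 3 libraries, 12 in all. The libraries held between 13892258 and 17148686 reads in genes, detected between 16998 and 17602 genes, and gave the 10 most abundant genes between 3.81% and 4.60% of the reads. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The design addresses which transcripts depend on VGLL1 in these cells. It also allows responses common to all 3 siRNAs to be separated from responses that differ between siRNAs.

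VGLL1 was lower in all 9 VGLL1 siRNA libraries than in any control library. Its normalised read count was 527 ± 36.3 in control (SD, n = 3), 193 ± 16.9 with siRNA 1, 27.1 ± 7.37 with siRNA 2 and 58.6 ± 15.1 with siRNA 3. These levels were 36.6%, 5.15% and 11.1% of control. On the log2 scale VGLL1 fell by 1.45, 4.26 and 3.17 with siRNAs 1, 2 and 3 (SE 0.18 for each siRNA; limma adjusted p = 3.48e-06, 1.02e-12 and 9.45e-11). The siRNAs also differed from one another: VGLL1 was lower with siRNA 3 than with siRNA 1 by 1.73 (limma adjusted p = 1.91e-07), and siRNA 2 left less than siRNA 3 (log2 difference −1.09, limma adjusted p = 3.91e-05). VGLL2 was near the limit of detection, with between 1 and 4 reads over the 3 libraries of each group.

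Of the TEAD factors, TEAD4 was lower with each siRNA (log2 fold change −0.25, −0.29 and −0.24, SE 0.05). TEAD2 fell by 0.39 with siRNA 1 and by 0.32 with siRNA 2, and its value with siRNA 3 was −0.06 (limma adjusted p = 0.36). TEAD1 fell by 0.22 and 0.26 with siRNAs 1 and 2 and rose by 0.15 with siRNA 3. TEAD3 fell by 0.24 with siRNA 2, with values of −0.14 with siRNA 1 (limma adjusted p = 0.09) and −0.14 with siRNA 3 (0.08). YAP1, the co-activator that competes for TEAD, fell by 0.98 with siRNA 2 (SE 0.06), against 0.22 with siRNA 3 and a value of −0.09 with siRNA 1 (limma adjusted p = 0.27). Its paralog WWTR1 fell by 0.21 with siRNA 2 and 0.30 with siRNA 3. VGLL3 fell by 0.22 and 0.70 with siRNAs 1 and 2 and rose by 0.37 with siRNA 3. VGLL4 rose by 0.15 with siRNA 3, with values of 0.05 and 0.02 with siRNAs 1 and 2 (limma adjusted p = 0.50 and 0.76).

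**Figure D1:**
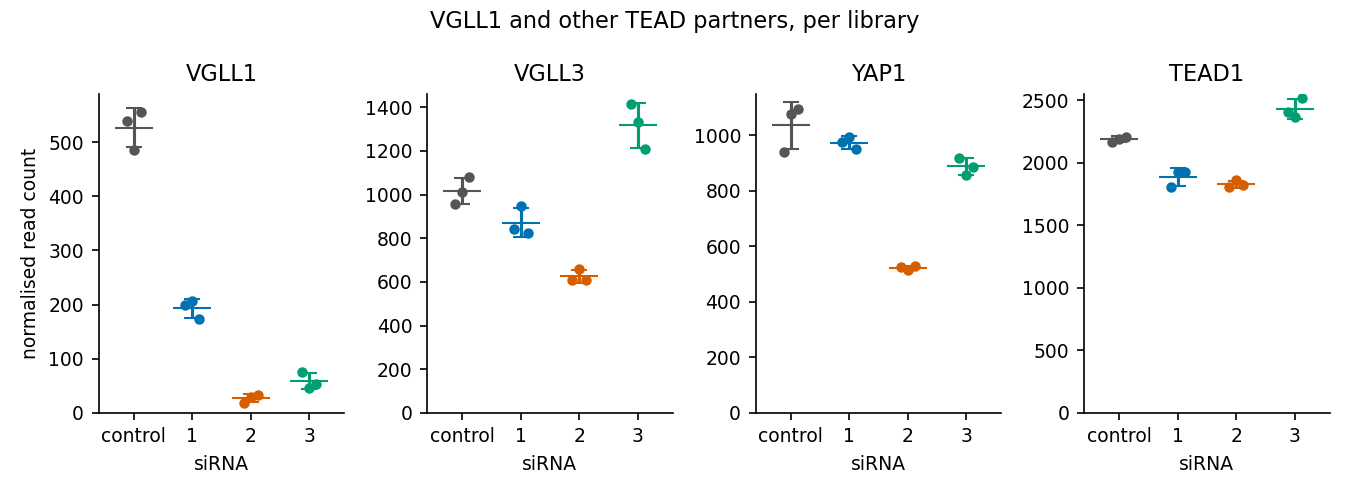
Normalised read count (vertical axes, each from 0) of VGLL1, VGLL3, YAP1 and TEAD1 in each library (points), with group means (horizontal lines) and SD (bars), for control siRNA and VGLL1 siRNAs 1, 2 and 3. VGLL1 means were 527, 193, 27.1 and 58.6, while VGLL3 was lower with siRNA 2 (625) and higher with siRNA 3 (1318) than in control (1016).

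Principal components of the log2 normalised counts separated the 4 groups. Component 1, with 34.8% of the variance, set siRNA 2 and siRNA 3 at opposite ends. Component 2 (24.6%) set siRNA 1 apart, and component 3 (12.2%) set the control libraries apart from all 9 VGLL1 siRNA libraries. Between libraries of one group, counts over genes differed by more than sampling noise in every one of the 12 pairs (chi-square per degree of freedom from 1.91 to 4.81), and the 54 pairs from different groups gave 15.4 to 36.4, so that no library was a duplicate of another.

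**Figure D2:**
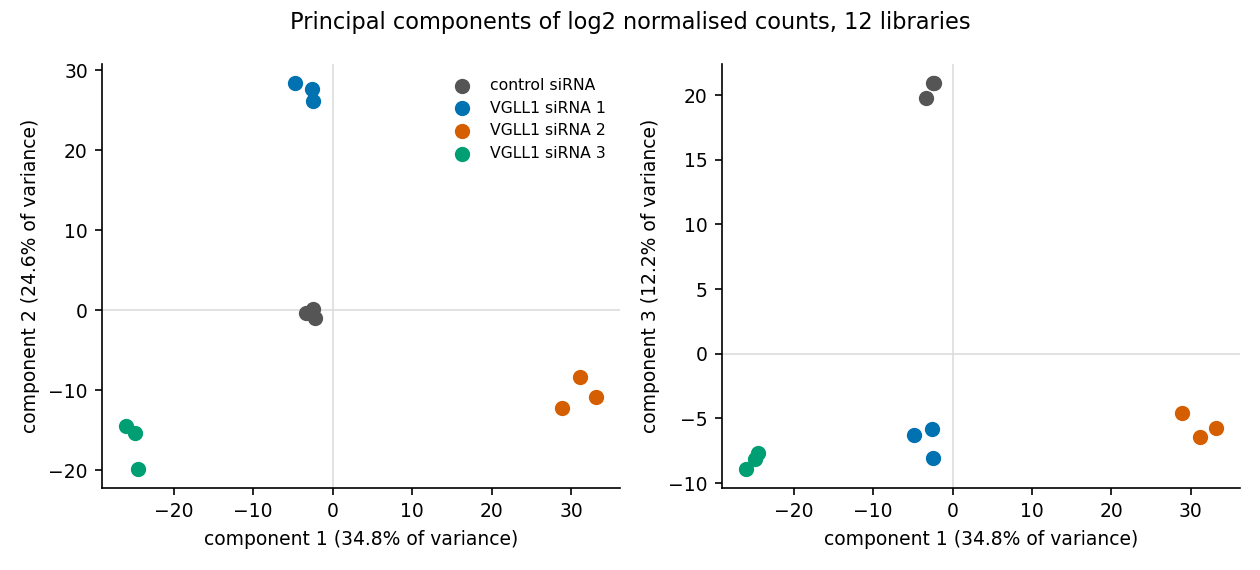
Principal components of log2 normalised counts for the 12 libraries (points, coloured by group): component 1 against component 2 on the left and against component 3 on the right, in arbitrary units. Component 1 (34.8% of variance) parts siRNA 2 from siRNA 3, and component 3 (12.2%) parts control from the 9 other libraries.

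With siRNA 1 the most uniform change was a rise of interferon response genes: 35 of 38 measured members were higher than in control and 1, TAP1, was lower (35 and 1 also adjusted over the list alone). The median over the list was a log2 fold change of 0.98. IFIT1 and IFIT2, which encode interferon-induced proteins that bind RNA, rose by 1.95 and 1.83 (SE 0.15 and 0.11). The list test gave a camera adjusted p of 8.85e-33 (adjusted p = 0.0635 with an estimated correlation). Of 25 targets of p53, 22 rose, with a median of 0.51, among them GADD45A (0.93) and SESN2 (0.69), and BTG2 fell by 0.24 (adjusted over the list alone 22 and 2; camera adjusted p = 4.83e-15, and adjusted p = 0.0310 with an estimated correlation). Of 19 immediate early genes 14 were higher, with KLF2 at 1.07 and EGR1 at 0.72, and 1, MYC, was lower (adjusted over the list alone 14 and 1; camera adjusted p = 3.46e-09, and adjusted p = 0.0310 with an estimated correlation). Of 17 genes induced by MAPK signalling 12 rose, including the phosphatases DUSP4 (1.14) and DUSP5 (1.33), and SPRED1 and EPHA4 fell (adjusted over the list alone 13 and 2; camera adjusted p = 0.000128, and adjusted p = 0.0788 with an estimated correlation). NF-kB target genes rose in 10 of 12 cases, with BIRC3 at 0.92, while PTGS2 fell by 1.31 (adjusted over the list alone 10 and 1; camera adjusted p = 9.81e-06, and adjusted p = 0.0310 with an estimated correlation).

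Mesenchymal and adhesion genes were lower with siRNA 1. Of 14 mesenchymal genes 7 fell and none rose, with TGFBI at −1.46 and COL5A1 at −1.02 (adjusted over the list alone 7 and 0; camera adjusted p = 0.000128, and adjusted p = 0.0352 with an estimated correlation). Of 18 integrin and laminin genes 12 fell, including ITGB6 (−1.27), and 2 rose, LAMB3 by 0.87 and ITGB4 by 0.15 (adjusted over the list alone 13 and 2; camera adjusted p = 9.45e-05, and adjusted p = 0.210 with an estimated correlation). Of 20 targets of YAP and TEAD 11 fell, IGFBP3 by 1.34 and NT5E by 0.79 among them, and 2 rose, GADD45A and MYOF (adjusted over the list alone 11 and 2; camera adjusted p = 0.000350, and adjusted p = 0.105 with an estimated correlation). Luminal markers went both ways, with 4 of 14 higher, KRT19 at 0.54 among them, and 5 lower, of which AR, the androgen receptor, fell by 1.25 and TBX3 by 1.00 (adjusted over the list alone 4 and 5; camera adjusted p = 0.435). The genes furthest from control that also differed from both other siRNAs were CYP1A1 (2.65), ALDH3A1 (2.62), the imprinted long non-coding RNA H19 (2.57) and the heat shock gene HSPA6 (2.33). In all, 3999 of 13441 tested genes passed limma's test, 1883 higher and 2116 lower, and 166 and 78 of these changed at least 2-fold.

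With siRNA 2 interferon genes again rose, 30 of 38 with a median of 0.73, and IRF1 was the 1 member that fell (30 and 1 also adjusted over the list alone; camera adjusted p = 1.08e-16, and adjusted p = 0.224 with an estimated correlation). Genes of the integrated stress response, the ATF4-driven programme that follows arrest of translation initiation, rose in 14 of 22 cases. CHAC1, which degrades glutathione, rose by 2.01 and the cystine transporter SLC7A11 by 1.19, while VLDLR and DDIT4 fell by 1.10 and 0.73 (adjusted over the list alone 14 and 2; camera adjusted p = 1.93e-06, and adjusted p = 0.0117 with an estimated correlation). MAPK-induced genes rose in 11 of 17 cases, with DUSP4 at 1.44 and ETV4 at 1.04, and EGR1 was the 1 that fell (adjusted over the list alone 12 and 1; camera adjusted p = 2.49e-05, and adjusted p = 0.145 with an estimated correlation). The EGFR ligand TGFA rose by 1.58 and the receptor ERBB2 fell by 0.59.

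Lineage genes moved with siRNA 2 as well. Of 14 luminal markers 9 fell and none rose, with a median of −0.23, while 8 of 16 basal markers rose and none fell, with a median of 0.38 (adjusted over the list alone 9 lower and 1 higher of the luminal, 8 higher and 1 lower of the basal; camera adjusted p = 2.53e-05 and 0.00239, and adjusted p = 0.150 and 0.323 with an estimated correlation). Of 32 oxidative phosphorylation genes 18 fell, by a median of 0.15 over the list (18 also adjusted over the list alone; camera adjusted p = 0.000139, and adjusted p = 0.347 with an estimated correlation). The genes furthest from control and different from both other siRNAs were VGLL1 itself, SPTSSB, a small subunit of serine palmitoyltransferase (3.00), CAPN6 (−2.97) and VTCN1, an immune checkpoint ligand (−2.95). In all, 4616 genes passed limma's test, 2266 higher and 2350 lower, with 163 and 190 changed at least 2-fold.

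With siRNA 3 genes of the MAPK list were lower. Of 17 measured 12 fell and 1, EPHA4 (0.29), rose, with a median of −0.56 (adjusted over the list alone 14 and 1; camera adjusted p = 2.57e-05, and adjusted p = 0.233 with an estimated correlation). ETV4, a transcription factor of the PEA3 family, fell by 3.20 (SE 0.19) and EGR1 by 1.23. With siRNA 3 ETV4 was near the floor, at 5.60, 5.83 and 3.83 normalised counts, so the size of its fall is uncertain (−3.40 with edgeR). Of the p53 targets 15 of 25 fell, among them TNFRSF10B (−0.72), and 3 rose, RRM2B, TP53I3 and TIGAR (adjusted over the list alone 16 and 5; camera adjusted p = 0.00272, and adjusted p = 0.489 with an estimated correlation). None of the 12 NF-kB genes rose past limma's test and 6 fell (6 also adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.233 with an estimated correlation). S phase genes were lower in 14 of 34 cases and higher in none (adjusted over the list alone 15 and 0; camera adjusted p = 0.00324, and adjusted p = 0.489 with an estimated correlation). Interferon genes rose here too, 18 of 38 with a median of 0.22, and TAP1 and IFITM1 fell (adjusted over the list alone 19 and 3; camera adjusted p = 0.0157, and adjusted p = 0.847 with an estimated correlation). The mean over the list was 0.10.

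The genes furthest from control with siRNA 3 and different from both other siRNAs were ETV4, the gelatinase MMP9 (−2.80), the hair keratin KRT81 (−2.71) and PLEKHA4 (−2.53). Reads of KRT81 may be shared with near-identical keratins, so its value is uncertain. In all, 5242 genes passed limma's test, 2522 higher and 2720 lower, with 68 and 150 changed at least 2-fold.

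All 3 siRNAs moved 526 genes the same way, 200 higher and 326 lower, each past limma's test against control with each siRNA. Most of these changes were small: median log2 fold changes of the 200 genes were 0.32, 0.33 and 0.32 with siRNAs 1, 2 and 3, and those of the 326 were −0.31, −0.33 and −0.34. Of these, 2 of the 200 and 8 of the 326 changed at least 2-fold with every siRNA. The 2 were ALDH3A1, given next, and CD109, a surface antigen, at 1.07, 1.14 and 1.02.

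The 12 shared rises with the largest smallest effect were taken among genes with a mean of at least 50 normalised counts. Of these, ALDH3A1, an aldehyde dehydrogenase, rose by 2.62, 1.15 and 1.47 with siRNAs 1, 2 and 3 (SE 0.23), and the cytochrome P450 gene CYP1A1 by 2.65, 1.73 and 0.73 (SE 0.15). Of the immediate early genes among the 12, KLF2 rose by 1.07, 0.95 and 1.70, KLF6 by 0.75, 0.70 and 1.02, and ATF3, which responds to stress, by 1.01, 1.19 and 0.74. FAM129A rose by 1.06, 2.77 and 0.80, IFIT1 by 1.95, 1.49 and 0.67, and the keratin KRT16 by 2.04, 0.58 and 0.70. RAB27B, a GTPase of vesicle secretion, GOLGA7B, C1orf116 and PCLO completed the 12, with values between 0.56 and 1.35. PCLO was the least secure of them, higher than every control library in 8 of 9 libraries, where the other 23 shared genes named here were beyond every control library in 9 of 9. Its mean over the 3 siRNAs was 0.61, and 0.46 without control replicate 1 (limma adjusted p = 0.011 and 0.103).

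The 12 leading shared falls by the same rule, after VGLL1, included MGP, the matrix Gla protein that inhibits calcification, at −1.98, −1.59 and −1.24 with siRNAs 1, 2 and 3 (SE 0.11). NR2F1, an orphan nuclear receptor, was at −1.08, −1.16 and −1.69 (SE 0.09), and its antisense RNA NR2F1-AS1 at −1.01, −1.24 and −1.17. The library kit as named does not mark strand, so reads of NR2F1 and NR2F1-AS1 cannot be told apart where the genes overlap. CAPN6, a calpain, was at −1.97, −2.97 and −0.94, and the transcription co-factor LBH at −1.55, −0.79 and −1.54. FZD8, a Wnt receptor, was at −0.78, −1.35 and −0.94. CD14, the co-receptor for lipopolysaccharide and one of the leukocyte markers, was at −0.97, −2.45 and −1.25. The protease inhibitor TFPI2, the endothelin EDN2, the receptor GPRC5B and MDGA1 lay between −0.68 and −1.24.

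**Figure D3:**
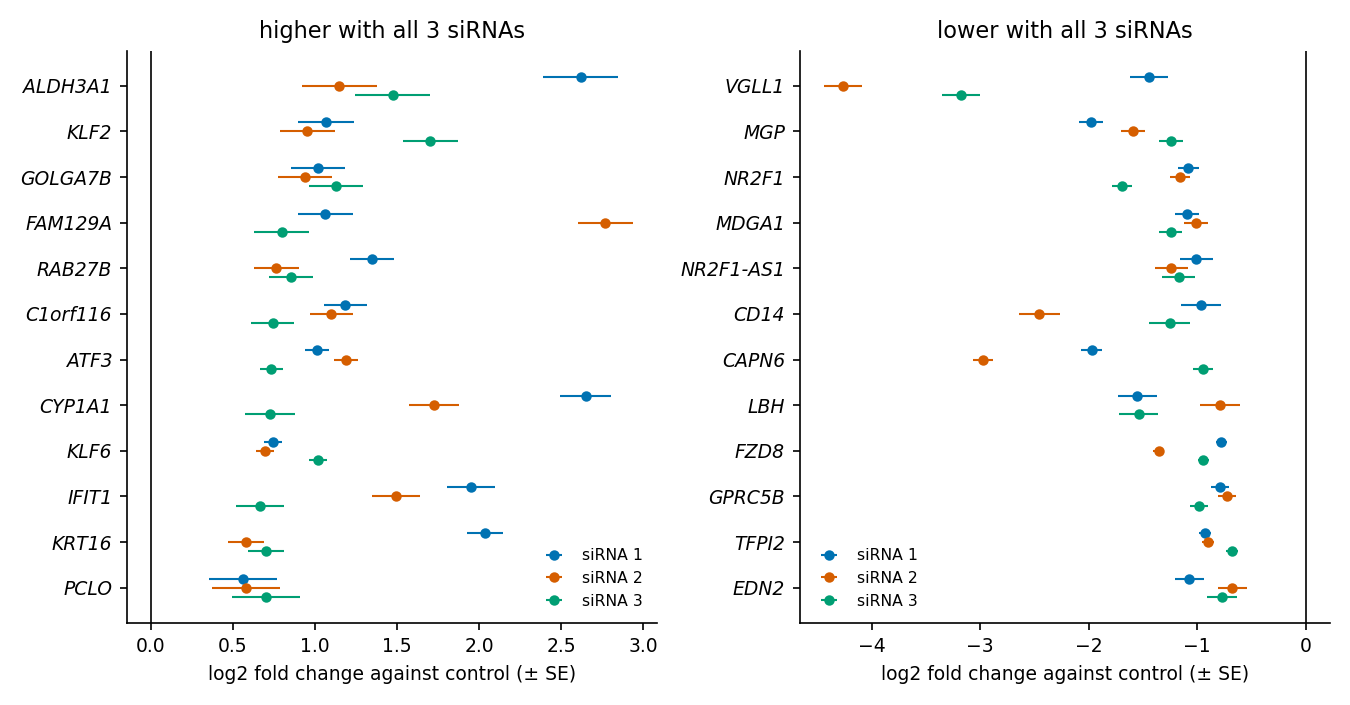
Log2 fold change against control (horizontal axes, bars ± SE) for the 12 rising and 12 falling genes with the largest smallest effect among genes with a mean of at least 50 normalised counts changed the same way by all 3 siRNAs, n = 3 libraries per group. CYP1A1 ranged from 0.73 to 2.65 between siRNAs and MGP from −1.98 to −1.24.

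Of the fixed lists, the interferon genes contributed the most members to the shared set, 17 of 38, all higher and led by IFIT1 and IFIT2. Immediate early genes contributed 4 of 19, namely ATF3, KLF2, KLF6 and NR4A1. The list of chaperones and sensors of endoplasmic reticulum stress contributed 5 of 18, all lower: HSP90B1, SEL1L, PDIA4, PDIA6 and CALR. Further members of the lists in the shared set were LAMB3, KRT16, MYOF, IGF1R, ATF4, HMOX1, TP53I3 and AGO4, which rose, and NT5E, IGFBP3, TGFBI, ERBB2, NRG2, SCD, SREBF1, PFKFB3, LDHA, NDUFA2, NDUFA4, ITGAV, ITGB5, MCM2, CELSR2, TM7SF2, VLDLR and TEAD4, which fell. The call of HMOX1 with siRNA 2 (0.27) was lost with edgeR (adjusted p = 0.0614).

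Comparisons against the same 3 control libraries share their chance values. Simulated unchanged groups against such controls gave 0 genes moving the same way with all 3 siRNAs in each of 20 simulations. Such groups give hardly any calls, with at most 1 gene moving the same way in any pair, so this 0 was fixed in advance. Independent lists of the observed sizes would share 59.6 higher and 74.9 lower genes, against the observed 200 and 326, but they leave out the shared controls. With control replicate 1, 2 or 3 left out of the fit, 397, 427 and 400 genes apart from VGLL1 moved the same way with all 3 siRNAs. In the direction of their call, the mean of the 9 VGLL1 siRNA libraries lay at a median log2 difference of 0.33, 0.33 and 0.33 from the left-out library (lower quartiles 0.22, 0.21 and 0.23), and all 3 siRNA means lay on the called side of it in 97.5%, 97.2% and 98.5% of the genes. Across genes, which are not independent replicates, the log2 fold changes of siRNAs 1 and 2 correlated at 0.24, of siRNAs 1 and 3 at 0.23 and of siRNAs 2 and 3 at 0.09. Their covariances were 0.0308, 0.0263 and 0.0117, against simulated values of 0.0123, 0.0122 and 0.0123, which leaves differences of 0.0185, 0.0141 and −0.00059. With a separate control library for each siRNA, over the 6 ways to assign them, the covariances ran from 0.0166 to 0.0209, from 0.0127 to 0.0167 and from −0.00311 to 0.0027.

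Averaged over the 3 siRNAs, 3389 genes differed from control by limma's test, 1508 higher and 1881 lower, with 31 and 40 changed at least 2-fold. In a model that treats the 9 VGLL1 siRNA libraries as one group, so that differences between siRNAs count as spread, 171 genes passed, 51 higher and 120 lower.

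Of 29 fixed lists with at least 5 measured members, 16 passed camera with its preset correlation in this average, 7 upwards and 9 downwards, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. For single siRNAs, the calls that held with an estimated correlation were those given above for p53 targets, immediate early, NF-kB and mesenchymal genes with siRNA 1 and for the integrated stress response with siRNA 2, and the integrated stress response with siRNA 1 (adjusted p = 0.0459). The counts that follow are members past limma's test over all genes, and those adjusted over the list alone stand in brackets.

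Interferon genes led the upward lists in the average, with 34 of 38 higher and 1, TAP1, lower (adjusted over the list alone 35 and 1; camera adjusted p = 1.57e-28, and adjusted p = 0.194 with an estimated correlation). TAP1 averaged −0.27 and lost its call without control replicate 1 (−0.23, limma adjusted p = 0.150) or 3 (−0.25, 0.114). Of 22 integrated stress response genes 11 were higher, with CHAC1 at 0.92, and 4 lower (adjusted over the list alone 12 and 4; camera adjusted p = 0.000342, and adjusted p = 0.0598 with an estimated correlation). By edgeR, CHAC1 was at 0.67, 2.01 and 0.05 with siRNAs 1, 2 and 3. Of 25 p53 targets 12 were higher and 2 lower (adjusted over the list alone 14 and 2; camera adjusted p = 3.78e-05, and adjusted p = 0.195 with an estimated correlation). Of 19 immediate early genes 9 were higher and 3 lower, with KLF2 at 1.24 and EGR1 at −0.24 (adjusted over the list alone 9 and 3; camera adjusted p = 0.000414, and adjusted p = 0.194 with an estimated correlation). Of 12 NF-kB genes 6 were higher and none lower (adjusted over the list alone 7 and 1; camera adjusted p = 0.0104, and adjusted p = 0.194 with an estimated correlation). Of 19 NRF2 targets 7 were higher and none lower, led by the haem oxygenase HMOX1 at 1.03 and SLC7A11 at 0.60 (adjusted over the list alone 7 and 1; camera adjusted p = 0.00514, and adjusted p = 0.203 with an estimated correlation). Of 16 basal markers 6 were higher, led by KRT16 (1.11) and LAMB3 (0.68), and 1, CDH3, lower (adjusted over the list alone 6 and 1; camera adjusted p = 0.00524, and adjusted p = 0.312 with an estimated correlation). CDH3 averaged −0.15, and −0.12 without control replicate 2 (limma adjusted p = 0.0730).

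Downwards, 10 of 18 genes of the endoplasmic reticulum stress list were lower, with CRELD2 at −0.35 and SEL1L at −0.34, and 1, DNAJB9, higher (adjusted over the list alone 13 and 1; camera adjusted p = 3.78e-05, and adjusted p = 0.235 with an estimated correlation). DNAJB9 averaged 0.20, with 0.18 without control replicate 1 and 0.15 without control replicate 3 (limma adjusted p = 0.0659 and 0.119). Of 34 mitotic genes 9 were lower, with ANLN at −0.25 and KIF20A at −0.23, and none higher (adjusted over the list alone 10 and 0; camera adjusted p = 0.000526, and adjusted p = 0.195 with an estimated correlation). By edgeR, ANLN was at −0.33, −0.12 and −0.32 with siRNAs 1, 2 and 3 and KIF20A at −0.33, −0.37 and 0.02. Of 24 cholesterol synthesis genes 10 were lower, with TM7SF2 at −0.29, and 1, HMGCS1, higher (adjusted over the list alone 10 and 1; camera adjusted p = 0.000922, and adjusted p = 0.195 with an estimated correlation). Of 10 fatty acid synthesis genes 5 were lower, with the regulator SREBF1 at −0.39 and the desaturase SCD at −0.36, and 1, ACSL3, higher (adjusted over the list alone 5 and 1; camera adjusted p = 0.0330, and adjusted p = 0.259 with an estimated correlation). Of 14 luminal markers 6 were lower and 1, KRT19, higher (adjusted over the list alone 6 and 2; camera adjusted p = 0.0146, and adjusted p = 0.293 with an estimated correlation). KRT19 averaged 0.16, and 0.15 without control replicate 3 (limma adjusted p = 0.0582).

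The list of VGLL, TEAD and Hippo pathway genes, which contains the targeted gene, had 9 of 22 lower and none higher in the average (adjusted over the list alone 9 and 0; camera adjusted p = 0.00382, and adjusted p = 0.235 with an estimated correlation). It was not lower with every siRNA. With siRNA 1, 9 were lower and 2 higher, and with siRNA 2, 13 and 2 (adjusted over the list alone 10 and 2, and 14 and 2; camera adjusted p = 0.00436 and 1.52e-05, and adjusted p = 0.210 and 0.150 with an estimated correlation). With siRNA 3, 9 were higher and 5 lower, with a median of 0.05 (adjusted over the list alone 10 and 5; camera adjusted p = 0.375). Against siRNA 3 the list was at a median of −0.22 with siRNA 1 and −0.29 with siRNA 2 (camera adjusted p = 0.0188 and 3.52e-05, and adjusted p = 0.402 and 0.148 with an estimated correlation). Of 14 mesenchymal genes 4 were lower and none higher, TGFBI (−0.68), COL5A1 (−0.33), THBS1 and TAGLN (adjusted over the list alone 4 and 0; camera adjusted p = 0.0355, and adjusted p = 0.203 with an estimated correlation). COL5A1 was at −1.02 with siRNA 1 and at −0.01 and 0.04 with siRNAs 2 and 3. Of 32 oxidative phosphorylation genes 6 were lower and none higher, with NDUFA4 at −0.32 (adjusted over the list alone 6 and 0; camera adjusted p = 0.0299, and adjusted p = 0.582 with an estimated correlation). Of 33 ribosomal protein genes 4 were lower, with RPS28 at −0.28, and none higher (adjusted over the list alone 2 and 0; camera adjusted p = 0.0367, and adjusted p = 0.675 with an estimated correlation). Ribosomal protein genes have many processed copies that can take part of their reads.

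In 8 of the 16 lists that passed in the average, camera's direction was not the same with all 3 siRNAs. These were the VGLL, TEAD and Hippo list, the p53 and NF-kB lists, lower with siRNA 3 as given above, and 5 others. With siRNA 2, mesenchymal genes were higher in 4 cases and lower in 1 (adjusted over the list alone 4 and 1; camera adjusted p = 0.0488, and adjusted p = 0.244 with an estimated correlation), and fatty acid synthesis genes were higher in 4 and lower in 3 (adjusted over the list alone 4 and 3; camera adjusted p = 0.451). With siRNA 3, luminal markers were higher in 4 cases and lower in 3, and integrated stress response genes in 5 and 7 (adjusted over the list alone 4 and 4, and 6 and 7; camera adjusted p = 0.605 and 0.799). With siRNA 1, oxidative phosphorylation genes were higher in 2 cases and lower in 3 (adjusted over the list alone 2 and 2; camera adjusted p = 0.695). Of the other 8 lists, 2 passed camera with each siRNA at the preset correlation, the interferon and the endoplasmic reticulum stress genes. With an estimated correlation neither passed with any siRNA. For the endoplasmic reticulum stress genes, camera adjusted p was 0.00112, 0.00976 and 0.00272 with siRNAs 1, 2 and 3 (adjusted p = 0.324, 0.411 and 0.567 with an estimated correlation). The other 6 lists did not pass with each siRNA. Basal markers with siRNA 1 were higher in 4 cases and lower in 6, with a median of 0.01 (adjusted over the list alone 4 and 6; camera adjusted p = 0.711). With siRNA 3, NRF2 targets were higher in 4 cases and lower in 4, with a median of −0.01, and immediate early genes in 6 and 5, with a median of −0.04 (adjusted over the list alone 4 and 4, and 6 and 6; camera adjusted p = 0.806 and 0.646). Also with siRNA 3, cholesterol synthesis genes were higher in 4 cases and lower in 5, ribosomal protein genes in 4 and 6, and mitotic genes in 1 and 10 (adjusted over the list alone 4 and 6, 3 and 6, and 1 and 10; camera adjusted p = 0.605, 0.573 and 0.188).

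The remaining 13 lists did not pass camera in the average, and for the EGFR family, trophoblast and G1 lists the median, the mean and the test differed in sign. Targets of YAP and TEAD gave 4 higher and 8 lower of 20 (adjusted over the list alone 4 and 9; camera adjusted p = 0.0969). Beside the falls with siRNA 1 given above, 8 were higher and 6 lower with siRNA 2, and 3 and 8 with siRNA 3 (adjusted over the list alone 8 and 6, and 4 and 9; camera adjusted p = 0.139 and 0.158). The list was at a median of −0.19 for siRNA 1 minus siRNA 2 and at 0.16 for siRNA 2 minus siRNA 3 (camera adjusted p = 0.000804 and 0.0295, and adjusted p = 0.293 and 0.373 with an estimated correlation). Within this list MYOF rose with each siRNA (0.91, 0.31 and 0.48), while the growth factor binding protein IGFBP3 (−1.34, −0.37 and −0.62) and the ectonucleotidase NT5E (−0.79, −0.60 and −0.62) fell with each. MAPK-induced genes gave 5 higher and 3 lower of 17 (adjusted over the list alone 5 and 3; camera adjusted p = 0.167). Integrin and laminin genes gave 2 higher and 6 lower of 18 (adjusted over the list alone 2 and 6; camera adjusted p = 0.244). S phase genes gave 1 higher and 6 lower of 34 (adjusted over the list alone 1 and 5; camera adjusted p = 0.422). With siRNA 2, integrin and laminin genes gave 8 higher and 5 lower and S phase genes 7 and 2 (adjusted over the list alone 9 and 6, and 7 and 2; camera adjusted p = 0.316 and 0.0550). Genes of ribosome biogenesis gave 6 higher and 2 lower of 25 (adjusted over the list alone 7 and 2; camera adjusted p = 0.0642), and glycolysis and hypoxia genes 7 and 6 of 25 (adjusted over the list alone 7 and 8; camera adjusted p = 0.422).

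The BCL2 family gave 5 higher and 2 lower of 20, with the BH3-only gene PMAIP1 at 0.47 (adjusted over the list alone 5 and 2; camera adjusted p = 0.118). Cyclins and kinases of G1 gave 5 and 4 of 16, with CDK6 at 0.38 and CCNE1 at −0.27 (adjusted over the list alone 5 and 5; camera adjusted p = 0.681). By edgeR, PMAIP1 was at 0.63, 0.84 and −0.07 with siRNAs 1, 2 and 3, CDK6 at 0.28, 0.75 and 0.12 and CCNE1 at −0.06, −0.60 and −0.15. Trophoblast markers gave 2 and 3 of 13 (adjusted over the list alone 2 and 3; camera adjusted p = 0.547), and the RNA interference machinery 3 and 1 of 13, with AGO4 at 0.43 (adjusted over the list alone 3 and 2; camera adjusted p = 0.383). Endothelial markers gave 0 and 1 of 5, CDH5 at −0.61 (adjusted over the list alone 1 and 1; camera adjusted p = 0.970). Fibroblast and leukocyte markers had 3 and 4 measured members, too few for the list test.

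**Figure D4:**
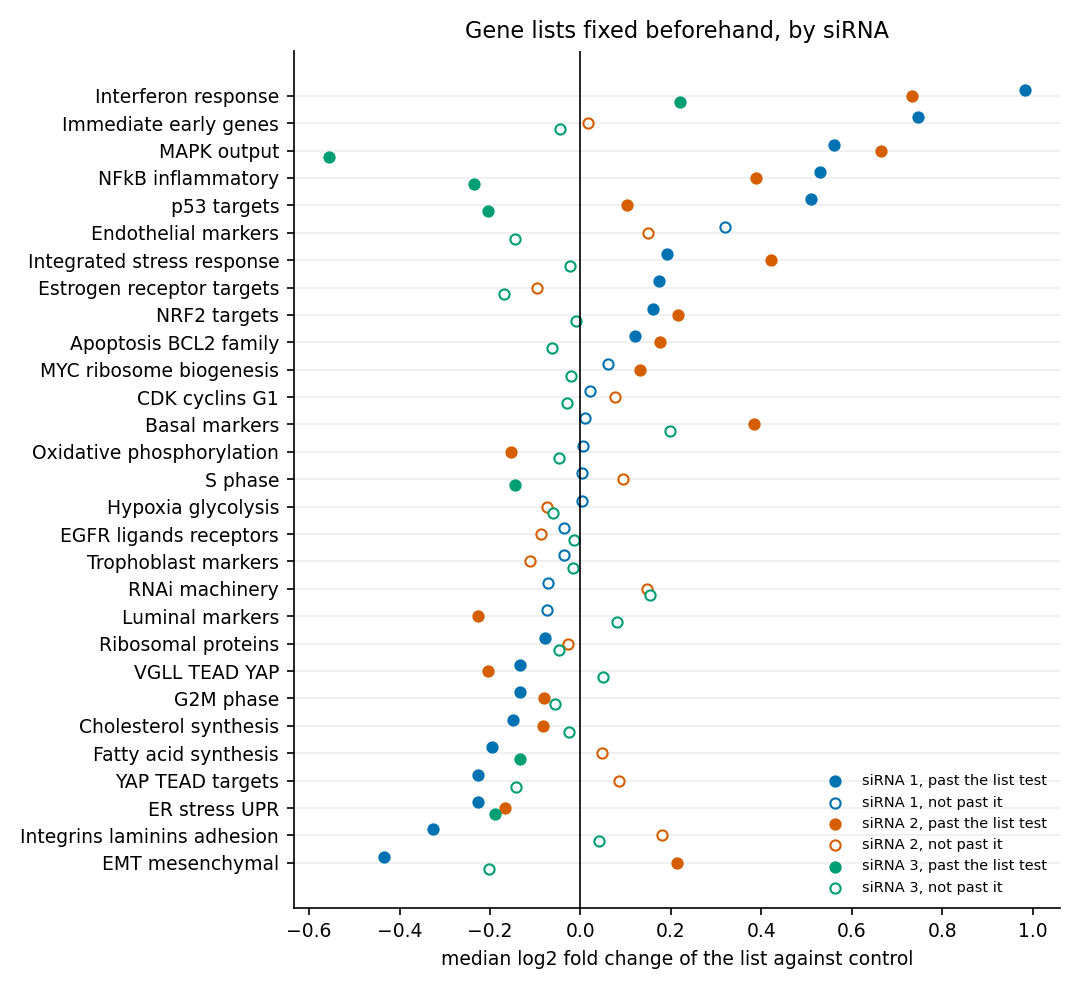
Median log2 fold change against control (horizontal axis) of the 29 gene lists fixed beforehand, by siRNA; filled points passed camera with its preset correlation and open points did not, n = 3 libraries per group. Interferon medians were 0.98, 0.73 and 0.22 with siRNAs 1, 2 and 3, and MAPK-induced genes were at 0.56, 0.66 and −0.56.

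Oestrogen receptor signalling and EGFR were of interest because the cells resist an oestrogen receptor degrader. ESR1, which encodes the oestrogen receptor, was low in control, with a normalised count of 76.3 ± 12.9 (SD, n = 3), and its targets TFF1 and PGR were near the limit of detection, with between 1 and 6 reads over the libraries of each group. ESR1 rose by 0.63 with siRNA 1 and by 0.40 with siRNA 3, and its value with siRNA 2 was −0.15 (limma adjusted p = 0.45). Over the 3 siRNAs it averaged 0.29 (limma adjusted p = 0.0851), and this call depended on single libraries, with 0.42 without control replicate 1 and 0.34 without replicate 1 of siRNA 2 (limma adjusted p = 0.0325 and 0.0266). Of 23 measured oestrogen receptor targets 3 were higher and 3 lower in the average (adjusted over the list alone 3 and 3; camera adjusted p = 0.879). With siRNA 1, 11 were higher and 4 lower (adjusted over the list alone 11 and 5; camera adjusted p = 0.0428, and adjusted p = 0.0966 with an estimated correlation). With siRNA 2, 6 were higher and 7 lower, and with siRNA 3, 5 and 8 (adjusted over the list alone 6 and 8, and 5 and 9; camera adjusted p = 0.620 and 0.225). The list was higher with siRNA 1 than with siRNA 3, by a median of 0.21 (camera adjusted p = 0.0287, and adjusted p = 0.122 with an estimated correlation). The cyclin CCND1, on that list, rose by 0.56 and 0.66 with siRNAs 1 and 2 and fell by 0.28 with siRNA 3, and IGF1R rose with each siRNA (0.32, 0.44 and 0.40).

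EGFR was lower with siRNA 1 by 0.25 (SE 0.07), with values of −0.11 and 0.02 with siRNAs 2 and 3 (limma adjusted p = 0.22 and 0.83). The average was −0.11 (limma adjusted p = 0.139). In the average, of 10 measured EGFR family receptors and ligands 2 were higher, TGFA (0.76) and the feedback inhibitor ERRFI1 (0.48), and 3 lower, NRG2 (−0.86), ERBB2 (−0.29) and ERBB3, the last named after its value was seen (adjusted over the list alone 2 and 3; camera adjusted p = 0.586). By edgeR, TGFA was at 0.68, 1.55 and −0.03 with siRNAs 1, 2 and 3 (edgeR adjusted p = 0.0190, 3.88e-06 and 0.926). ERRFI1 was at 1.10, 0.20 and 0.13 (edgeR adjusted p = 3.48e-08, 0.147 and 0.344). Neither average therefore stands for all 3 siRNAs, while NRG2 and ERBB2 fell with each siRNA, as given above.

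The siRNAs differed from one another in more genes than any of them differed from control. Between siRNAs 1 and 2, 5818 genes differed (2887 higher with siRNA 1 and 2931 lower), between siRNAs 1 and 3, 6285 (3171 and 3114), and between siRNAs 2 and 3, 6580 (3365 higher with siRNA 2 and 3215 lower), all by limma's test. Control differed from all 3 other groups in the same direction in 526 genes, while siRNA 1, siRNA 2 and siRNA 3 differed so from their 3 other groups in 1637, 2099 and 2551 genes. Pairs of siRNAs moved genes in opposite directions in 630 (siRNAs 1 and 2), 717 (1 and 3) and 988 cases (2 and 3), where independent lists would give 686, 778 and 900.

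MAPK-induced genes were higher with siRNA 2 than with siRNA 3 in 16 of 17 cases and lower in none, by a median of 1.02 (adjusted over the list alone 16 and 0; camera adjusted p = 8.52e-10, and adjusted p = 0.0302 with an estimated correlation). NF-kB genes were also higher with siRNA 1 than with siRNA 3 in 10 of 12 cases and lower in 1, by a median of 0.87 (adjusted over the list alone 10 and 1; camera adjusted p = 5.66e-06, and adjusted p = 0.0438 with an estimated correlation). They were higher with siRNA 2 than with siRNA 3 in 8 of 12 cases and lower in 0, by a median of 1.08, and integrated stress response genes were higher in 14 of 22 and lower in 3, by 0.50 (adjusted over the list alone 8 and 0, and 15 and 3; camera adjusted p = 7.30e-05 and 0.000125, and adjusted p = 0.0302 and 0.0302 with an estimated correlation). p53 targets were higher with siRNA 1 than with siRNA 3 in 19 of 25 cases and lower in 2, by a median of 0.81 (adjusted over the list alone 19 and 2; camera adjusted p = 3.84e-12, and adjusted p = 0.0570 with an estimated correlation). Interferon genes were higher with siRNA 1 than with siRNA 2 in 23 of 38 cases and lower in 4, by a median of 0.40. Compared with siRNA 3 they were higher with siRNA 1 in 35 of 38 and lower in 0, by a median of 0.87 (adjusted over the list alone 23 and 4, and 36 and 0; camera adjusted p = 6.85e-05 and 3.26e-18, and adjusted p = 0.520 and 0.167 with an estimated correlation).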

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

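The tests of VGLL1 left and of the grading of interferon genes by VGLL1 loss were chosen after the results were seen, as were the thinning of reads, the interferon medians by library, the left-out and separate control libraries, the share of carriers of any word and the count of named genes that carry a word. The results given here are those in which 2 siRNAs moved a gene or list in opposite directions past the test and the direct difference between them passed as well, with the largest such difference for each.

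MAPK-induced genes were higher with siRNA 1 than with siRNA 3 by a median of 1.27 on the log2 scale (camera adjusted p = 2.16e-08, and adjusted p = 0.0570 with an estimated correlation). The p53 targets differed by 0.81 between the same siRNAs (camera adjusted p = 3.84e-12, and adjusted p = 0.0570 with an estimated correlation). NF-kB genes were higher with siRNA 2 than with siRNA 3 by 1.08 (camera adjusted p = 7.30e-05, and adjusted p = 0.0302 with an estimated correlation). Mesenchymal genes gave −0.57 for siRNA 1 minus siRNA 2 (camera adjusted p = 6.85e-05, and adjusted p = 0.0783 with an estimated correlation). The phosphatase DUSP4 was higher with siRNA 2 than with siRNA 3 by 1.87, ETV4 by 4.25, the gelatinase MMP9 by 3.72, CCND1 by 0.95, the chaperone HSPD1 by 1.09 and ADM by 1.05. ETV4 was near the floor with siRNA 3, so the size of its difference is uncertain. For siRNA 2 minus siRNA 3, VTCN1 was at −4.11, VGLL3 at −1.07, TFAP2C at −0.63 and TEAD1 at −0.41. Higher with siRNA 1 than with siRNA 3 were H19 by 3.41, PLEKHA4 by 3.31, EGR1 by 1.95, ACTA2 by 1.39, GADD45A by 1.12 and TNFRSF10B by 0.89. Higher with siRNA 1 than with siRNA 2 were DDIT4 by 1.02, CTSD by 0.86 and KRT19 by 0.78, while LAMC2 was at −0.96. The limma adjusted p of these genes was at most 1.59e-07, and in the 20 genes all 3 libraries of one siRNA lay beyond all 3 of the other.

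The first pattern weighed is that siRNAs differed from one another in more genes than from control. Different amounts of VGLL1 left are argued against as the source, since the pair with the closest VGLL1 levels, siRNAs 2 and 3 with a log2 gap of 1.09, differed in the most genes, 6580, and depth is argued against by the 96.0% of each count left, at the lowest, after thinning. Each siRNA had a 7-base word, also found in VGLL1, whose presence in the 3' UTR went with lower levels beyond every shuffle after adjustment for UTR length, GC content and gene level: CTCTCCT (t = −10.34, lowest shuffle −5.28), GATGAAC (−8.25 against −5.17) and CACTATA (−11.41 against −5.22, although without adjustment the median carrier was not lower than other genes, at 0.0102 against 0.00844), which is consistent with repression through the seed. Among falls specific to siRNAs 1, 2 and 3 carriers exceeded their share among other genes by 17.3, 8.63 and 1.82 percentage points for the leading word. The mean of 9.26 was under the 25 points below which seeds were set beforehand not to be the main source. For any of the 5, 1 and 3 words beyond every shuffle the excess was 19.1, 8.63 and −4.63 points. Unlike the t values, these shares were not adjusted for UTR length, GC content or gene level. They therefore cannot decide how much of the falls came through seeds, above all with siRNA 3, where adjustment changed the reading. Of the named genes that carry a word and passed with its siRNA, 17, 7 and 5 fell and 13, 6 and 4 rose with siRNAs 1, 2 and 3. The naming rule took rises and falls in similar numbers, so these counts cannot show how often carriers fell. Among all falls specific to siRNAs 1, 2 and 3, 38.6%, 15.5% and 8.52% carried the leading word. Among the specific rises the shares were 16.2%, 6.20% and 7.19%. Single carriers went both ways (with siRNA 2, YAP1 at −0.98 and FAM129A at 2.77). A word alone therefore does not mark a gene as a direct target, and secondary effects stay open.

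The second pattern is the 526 genes changed the same way by all 3 siRNAs. Simulated unchanged groups gave 0 such genes and independent lists 134, but the former leave out the siRNAs' effects and the latter the shared controls, so the bound set on them beforehand excludes nothing. Chance values of single control libraries are argued against as the whole source. Genes called with 2 control libraries lay, in the direction of the call, at a median of 0.33 from the third, whichever was left out (lowest lower quartile 0.21). The same siRNA libraries made the calls and this difference, so it does not bear on separate siRNA effects that happened to agree in sign. With separate control libraries, 168 to 187 genes passed with the same sign with all 3 siRNAs, against 114 to 119 for independent signs. Genes are not independent, however, and the covariance of siRNAs 2 and 3 ran only from −0.00311 to 0.0027. Release of genes repressed through 1 strong seed of the control siRNA is argued against by the highest word, at t = 3.89, below the highest shuffle at 5.45. The control siRNA's sequence is not given, and the scan does not cover repression spread over several words. A response to the loss of VGLL1 stays open, as does a chance value or an effect of the control siRNA common to all 3 control libraries, which cannot be told apart from it with 1 control group. Separate effects of the 3 siRNAs that agree in sign by coincidence stay open as well.

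The third pattern is the rise of interferon genes, with the highest median for siRNA 1. A response graded by the loss of VGLL1 over all 3 siRNAs is argued against by siRNA 1, which left the most VGLL1 and yet exceeded siRNA 3 by a median of 0.87 over the list (38 of 38 genes). Between the other siRNAs the order went with VGLL1 loss: siRNA 2 left less VGLL1 than siRNA 3 and exceeded it by a median of 0.59 (33 of 38 genes). List medians per library ran from 0.871 to 1.18 with siRNA 1, 0.592 to 0.804 with siRNA 2 and 0.0885 to 0.307 with siRNA 3, although by camera the differences of siRNA 1 from siRNAs 2 and 3 had adjusted p = 0.520 and 0.167 with an estimated correlation, and the gap to siRNA 2 was a median of 0.40. Leukocytes are argued against by a median marker of 1.28 normalised counts with siRNA 1, against 1.37 in control. Sensing of the siRNA duplexes themselves, in different degree, may account for the order but was not tested, and a part common to VGLL1 loss stays open.

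Other splits of the libraries were counted as well. For each siRNA against control and for each pair of siRNAs, 1 of 10 splits of the 6 libraries, the real one, gave as many genes (3999, 4616, 5242, 5818, 6285 and 6580 against 0 at the highest for the others), and 10 splits cannot give a share under 0.1. For the mean of the 3 siRNAs, 2 of 100 splits gave as many genes as the real 3389, and for genes changed the same way 3 of 100 gave as many as 526. Splits that mix libraries of different siRNAs put the differences between siRNAs into the spread, and the median over the 99 other splits was 0 for both. Splits with the libraries of siRNA 3, 2 or 1 in the control's place and the other libraries mixed gave 3492, 2785 and 1728 genes for the mean. They gave 1183, 977 and 452 changed the same way. The control libraries in that place, with the others mixed, gave only 133 and 12. The real 3389 and 526 come from unmixed groups and cannot be set against these. With unmixed groups the counts changed the same way were 526 for control and 1637, 2099 and 2551 for siRNAs 1, 2 and 3. The control group therefore did not stand out from the siRNA groups by these counts, and the small shares do not exclude chance. For lists past camera, 2 of 100 splits gave as many as 16. The highest other, 17, mixed control and siRNA 3 libraries in the control's place, all 99 other splits gave some lists with a median of 6, and 0 lists passed with an estimated correlation, so that chance was not excluded for that count.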

How the results depend on the processing

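Tests with siRNAs 2 and 3 only, with thinned reads and with a 1.5-fold minimum were chosen after the result was seen. Of the main counts and the VGLL1 value, 237 recomputed values stayed within 1.5 times the original or kept direction and call, and 4 moved. Treating the 9 VGLL1 siRNA libraries as one group gave 171 genes (51 higher, 120 lower) in place of 3389, by its construction, since differences between siRNAs then count as spread. Camera with an estimated correlation gave 0 lists in place of 16, and 7 had an unadjusted p under 0.05. Counting only siRNAs 2 and 3 gave 1325 genes changed the same way in place of 526. By its construction, a rule for 2 siRNAs cannot give fewer genes than a rule for all 3. The pairs 1 and 2, and 1 and 3, gave 1305 and 1359. Independent lists would give 901 for siRNAs 2 and 3, and 687 and 782 for the other pairs. A 1.5-fold minimum for each siRNA gave 41 (16 higher, 25 lower). In the average of siRNAs 2 and 3 only, COL5A1 (0.014), H19 (−0.62) and KRT19 (−0.034) reversed, since siRNA 1 carried their values. The model with the 9 libraries as one group also left 94 of 120 named genes weaker in the average and 26 the same, for the same reason. Without control replicate 1, 2 or 3, 19, 16 and 14 of the 120 were weaker. Over all settings, single genes and lists were the same in 3393 cases, weaker in 228, those 94 included, and stronger in 7, and apart from the model with 1 group the cause was not tested. With the pseudocounts, filters, scalings, tests and libraries fixed beforehand, the counts ran from 3356 to 4058 for siRNA 1, 3838 to 4671 for siRNA 2, 4508 to 5376 for siRNA 3, and 404 to 535 for genes changed the same way, each lowest with DESeq2. With edgeR 514 of the 526 genes were among its 535. Leaving out 1 library at a time gave 3258 to 4065, 3832 to 4747 and 4447 to 5355 for siRNAs 1, 2 and 3, 2381 to 3460 for their mean, 398 to 507 for genes changed the same way, 5108 to 5873, 5481 to 6282 and 5841 to 6679 for the pairs 1 and 2, 1 and 3, and 2 and 3, 14 to 17 lists and −3.03 to −2.88 for VGLL1. In the simulated data, 1.25-fold rises were recovered in 52%, 47.5% and 50% of 50, 40 and 36 genes. That simulation gave 159, 152 and 156 calls for siRNAs 1, 2 and 3, against 3999, 4616 and 5242 in the data. With so few changed genes an adjusted p under 0.05 is harder to reach, so these shares do not give the recovery in the data.

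With the replicate number as a replicate block the counts were 3819, 4415 and 5068 for siRNAs 1, 2 and 3, 3169 for their mean, 473 for genes changed the same way, 5657, 6138 and 6434 for the pairs, 16 lists and −2.96 for VGLL1. Libraries of different groups with the same number correlated between −0.17 and 0.11 after removal of group means, 1 of 18 pairs above 0.1, so the libraries were analysed as unpaired.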

Other observations

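The test of genes induced through the aryl hydrocarbon receptor was chosen after CYP1A1 and ALDH3A1 had been seen among the shared rises. CYP1A1 rose from 153 normalised counts in control to 992, 507 and 253 with siRNAs 1, 2 and 3. CYP1B1, a related cytochrome P450 gene of the same pathway, rose from 621 to 2894 with siRNA 1 and to 1317 with siRNA 2 (log2 fold change 2.20 and 1.09), and was at 625 with siRNA 3 (0.01, limma adjusted p = 0.96). AHRR, the repressor of the receptor, rose with siRNA 1 (0.55, limma adjusted p = 0.0113), and TIPARP rose with siRNA 3 (0.48, limma adjusted p = 3.91e-05). The transporter ABCG2 rose with siRNAs 1 and 3 (0.55 and 0.76) and fell by 0.44 with siRNA 2. CYP1A2 rose with siRNA 1 (0.93) and siRNA 3 (1.48) from a low level of 11.4 counts, and NQO1 rose by 0.46 with siRNA 1 and fell by 0.11 with siRNA 2. NFE2L2 passed with none of the siRNAs.

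Markers of other cell types were at low medians. Leukocyte markers had medians of 1.37, 1.28, 1.20 and 1.12 normalised counts in control and with siRNAs 1, 2 and 3, with CD14 (125 in control) and, with siRNA 2, ITGAM (56.1) as the highest. Fibroblast markers had medians of 1.35, 1.97, 2.40 and 2.22, with COL1A1 at 1125 in control and 1020 with siRNA 3. Endothelial markers had medians of 12.3, 15.96, 17.5 and 11.8, with CDH5 at 253 in control and ESAM at 256 with siRNA 1.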
